A study of Mus musculus with 8 samples.

How the data were processed

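Lung sections of 8 mouse samples were assayed with a Xenium Prime in situ panel, a method in which barcoded probes bound to RNA are read by repeated imaging. Per the labels' protocols, bleomycin was given at 1.2 U/kg into the trachea of mice aged 10 to 12 weeks. Inhibitors were given by mouth from day 7, AZD3965 at 100 mg/kg and VB124 at 30 mg/kg, and lungs were taken at day 21. The left lung was fixed and embedded in paraffin. The label of each sample names 1 inhibitor or vehicle, and groups follow these labels; the design text names both inhibitors together, so whether any animal received both stays open. The sections lay on 2 slides, and the slide of each section is not given in the sources used here, so slide was not tested as a batch. The labels number the sections within a group and do not state that each came from a separate animal, so p-values measure only the spread between these sections, which may be technical.

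The authors deposited transcript counts per feature and segmented cell, whole numbers without normalization, per the file headers. Per the series design text, the instrument assigned transcripts to segmented cells; the software version, the quality filter on transcripts, the cell filter and the genome build are not given in the sources used here. The count matrices of the 2 control sections were used, and those of the other 6 sections were not analysed here. Lists of segmented cells from all 8 sections gave the number of cells. At most 19 cell identifiers were shared between any pair of sections. Of 13780 features in each matrix 5006 are genes, and these held 99.97% and 99.96% of counts; negative control probes, control codewords and unassigned or deprecated codewords were kept out of totals and tests. The 40 negative control probes had a mean of 2.25 counts in control section 1 and 5.70 in control section 2, and the highest had 12 and 20. Gene names are those of the deposited features, and no coordinates were used.

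Cells with at least 20 gene transcripts were kept, 125531 (97.1%) in control section 1 and 193965 (97.8%) in control section 2. The median number of genes per cell was 117 and 162, over all cells. The 12 gene lists held 360 genes, 229 of them on the panel, and took no part in clustering. From the other 4777 genes, 20000 cells per section were clustered on 2000 variable genes and 40 principal components, with each section centred, a graph of 20 neighbours and the Leiden method at resolution 2.5 (seed 1). All cells were then assigned to the 42 clusters by a multinomial likelihood after 5 refinements of the cluster profiles, which kept 77.3% of the clustered cells in their own cluster. No doublet caller was run, since cells come from segmentation.

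A cluster was named from fixed marker lists where at least 3 markers stood at a log2 fold of 1 or more over the other cells, with 20 CPM added to both sides. It also had to reach 0.7 of the marker score of the best cluster of its name, hold at least as many own markers as markers of any other class among its top 10 genes, and have at least 50 cells in each section. A runner-up type of the same compartment at 0.75 or more of the best score gave a joint name, as for dendritic-like cells and for monocyte and neutrophil-like cells. These shares and the minimum fold were set after the marker scores of the clusters had been seen and before any result of the listed genes. Of the 42 clusters 20 were left out. The clusters under 0.7 of the best score held 32.3% and 37.4% of cells, cycling clusters 0.189% and 0.164%, and a cardiomyocyte-like cluster had 0 cells in section 1 and 385 in section 2.

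Counts were summed per class and section into 44 libraries and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), using TMM factors, the filterByExpr minimum count of 10 and a quasi-likelihood fit with class and section as terms. The contrast of a compartment was the equal mean of its classes minus the equal mean of all other classes, and that of a class was the class minus the equal mean of the others. The standard error of a log2 fold change was its size divided by the root of the F statistic. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested and, beside it, over each list alone; for Slc16a1, Slc16a3, Ldha and Ldhb by class the adjustment was over these genes and classes together. The fry test was run for 12 lists in 4 compartments, adjusted over the 48 tests; it asks whether the genes of a list move on balance in a common direction, and does not compare the list with other genes. The fit held 4013 genes, 226 of them listed. Of these 23 had no count in at least 1 class in both sections, so that a mean of log levels over classes is undefined, and they were given no test; 3414 genes, 203 of them listed, were tested. This rule was chosen after results had been seen. Testing these genes gave 666 calls over the 4 compartments, leaving out only genes with such classes on both sides of a contrast gave 669, and the rule used gave 639.

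Gene lists, cell markers, tests and the rule for named genes were fixed before the data were examined, when the listed sizes of the files already showed the order of the sections in number of cells. The rule took Slc16a1, Slc16a3, Ldha and Ldhb throughout. Per compartment it took the 6 largest rises and 2 largest falls among called genes with the same direction in both sections. Per list it took up to 4 genes with the smallest p in the compartment with most calls of that list; 1 gene it took is not reported here. Genes named outside it were chosen after their values were seen: Pdk4 in epithelium, Slc5a12, Igf1, and the genes by class in the first paragraphs of the other observations. The lists covered lactate transport and pyruvate use, glycolysis, hypoxia response, mitochondrial oxidation, fatty acid metabolism, amino acid synthesis, acid and base sensing, acylation enzymes, matrix genes, TGF-beta signalling, inflammatory mediators, and stress and senescence.

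A simulation tested the contrast of immune classes with the others. Counts were drawn from each gene's mean level over all real libraries and its dispersion, with 200 genes changed. Each gene thus had 1 level in all classes apart from the planted change. Of the changed genes that passed the filter on low counts, 89.8% of changes of 0.5 and 96.8% of changes of 1 on the log2 scale were recovered. In all 3688 genes were tested, and 5% of calls were false. These rates were not measured where classes of a compartment differ, as they did in the real libraries. Levels are means of CPM (counts per class scaled to the library total) of a class over the 2 sections with their SD. Numbers of cells per section were compared with exact permutation tests, over all divisions of the 8 sections into 4 pairs and for 4 pairs of groups. Alternatives covered RLE factors, library totals alone, DESeq2 1.42.0, no filter on low counts, no section term, minimums of 10 and 40 transcripts per cell, a posterior of at least 0.99, cells summed per compartment, log2 cell numbers, a replicate block and each section left out. Cells summed per compartment weight each cell by its transcripts and replace the mean of logs by the log of a sum, so both choices change together. Others, chosen after the data were seen, left out classes, changed the rule for classes without a count, or added the clusters under 0.7 of the best score to the compartment of their best-scoring type. Clustering used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.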

Results

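The series measured transcripts in place in sections of mouse lung, in a model of lung fibrosis in which the transport of lactate across the cell membrane was blocked. Bleomycin, a drug that injures the lung and is followed by scarring, was given into the airway of male C57BL/6N mice, an inbred laboratory strain. The 8 sections fell into 4 groups of 2: vehicle without bleomycin (control), bleomycin with vehicle, bleomycin with AZD3965, and bleomycin with VB124. AZD3965 inhibits MCT1, the lactate transporter encoded by Slc16a1, and VB124 inhibits MCT4, encoded by Slc16a3. The assay read 5006 genes by imaging and assigned each transcript to a segmented cell. Segmented cells were counted in all 8 sections, 1594068 in total, and transcript counts per cell were analysed in the 2 control sections; those of the other 6 were not analysed here. Control section 1 held 23644427 gene transcripts with a median of 141 per cell, and control section 2 held 49400108 with a median of 198.

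The first comparison asked how the sections of the 4 groups differed in cell number. Both bleomycin sections held more segmented cells than any of the other 6 sections: 291427 and 231228, against a highest value of 202932 elsewhere. The group mean was 261328 ± 42567 (SD, n = 2) with bleomycin and vehicle, and 163882 ± 48845 (SD, n = 2) in controls. With AZD3965 the mean was 196492 ± 9108 (SD, n = 2), and with VB124 it was 175332 ± 28226 (SD, n = 2). The bleomycin mean was 1.59 times the control mean, and the means with AZD3965 and VB124 were 0.752 and 0.671 times the bleomycin mean.

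These differences did not pass a test. Over the 4 groups, 12 of the 105 divisions of the sections into pairs separated the means as much (exact permutation test, p = 0.114, smallest possible p 0.00952). The difference between bleomycin and control was 97445 cells, with a pooled SD within groups of 45814 (2-sided exact permutation test, p = 0.333). For AZD3965 against bleomycin it was -64836 cells, and for VB124 against bleomycin -85995 cells (2-sided exact permutation tests, p = 0.333 each). AZD3965 and VB124, which block different transporters and were given at different doses, differed by 21159 cells with a pooled SD of 20972 (2-sided exact permutation test, p = 0.667). A comparison of 2 sections with 2 cannot give an exact permutation p below 0.333, and the Benjamini-Hochberg adjusted values over the 4 comparisons were 0.444, 0.444, 0.444 and 0.667. Without the first-numbered sections the difference between bleomycin and control was 32807 cells, and without the second-numbered ones 162083; the number of cells also depends on the area of tissue in a section, which was not used here.

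**Figure D1:**
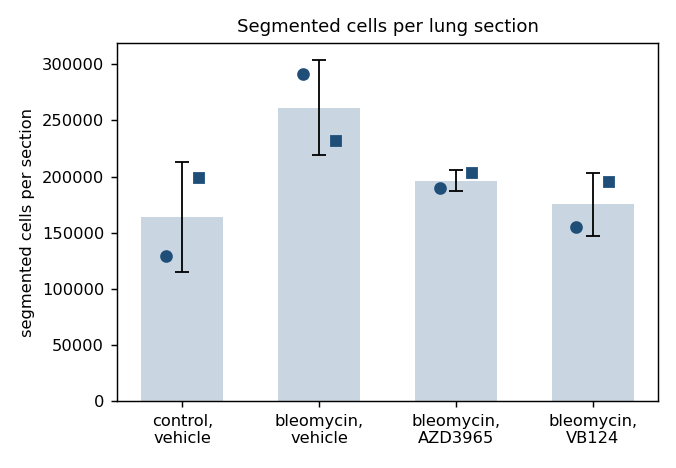
Segmented cells per lung section (y axis, number of cells) in the 4 groups (x axis). Bars are group means, error bars are SDs over 2 sections, and the circle and the square are the sections numbered 1 and 2; both bleomycin sections, at 291427 and 231228, lie above the other 6, the highest of which held 202932.

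The second account describes which cells made up the control lungs. Clusters carrying fixed marker genes gave 22 named classes, and 32.7% of cells in control section 1 and 37.9% in control section 2 stayed outside them. Named endothelial classes held 21.0% ± 5.06 of cells (SD, n = 2), epithelial classes 15.6% ± 0.349, immune classes 14.8% ± 1.23 and stromal classes 13.3% ± 0.502 (SD, n = 2 for each). General capillary-like endothelial cells were the most frequent named class, at 11.8% ± 3.71 (SD, n = 2), ahead of B cell-like cells at 5.81% ± 0.849 and alveolar type 2 (AT2)-like cells, which make surfactant, at 5.80% ± 0.879. Alveolar type 1 (AT1)-like cells, the thin cells across which gas exchange takes place, made up 5.37% ± 0.0841, and aerocyte-like capillary cells 5.07% ± 1.17 (SD, n = 2 for each). Adventitial fibroblast-like cells had the lowest mean share, with 373 cells in section 1 and 1677 in section 2. Clusters with a marker score under 0.7 of the best cluster of their name held 32.3% and 37.4% of cells and were left out of the classes, a limit set after the marker scores had been seen. With each of these clusters added to the compartment of its best-scoring type, which was tried after the data had been seen, the order of means reversed. Epithelial cells then held 30.4% ± 1.75 and endothelial cells 26.8% ± 6.35 (SD, n = 2 for each), with endothelial cells ahead in section 1, at 31.3% against 29.1%, and epithelial cells in section 2, at 31.6% against 22.3%. The largest cluster added to epithelium, with 6881 and 12410 cells, scored 0.988 for AT1 and 0.913 for general capillary cells. Another, with 2548 and 5945 cells, scored 1.17 for AT1 and 1.07 for alveolar fibroblasts. Its top 10 genes held 0 AT1 markers and 5 of alveolar fibroblasts. The reversal thus depends on the placement of such clusters, for which no alternative was run. The order of compartments and that of classes also changed among cells assigned with a posterior of at least 0.99: endothelial classes held 18.1%, below epithelial classes at 20.4% and immune classes at 18.5%, and general capillary-like cells held 7.02%, below AT2-like, B cell-like and AT1-like cells at 7.38%, 7.17% and 7.06%.

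The third comparison asked where in the uninjured lung the genes of lactate transport and of linked pathways were expressed, beginning with the targets of both inhibitors. Slc16a1 (ENSMUSG00000032902) was highest in mesothelial-like cells, which line the lung surface, at 2048 ± 298 CPM (counts scaled to a common library total; SD, n = 2). AT2-like cells followed at 261 ± 32.8, then T cell-like cells at 129 ± 12.1 and club-like cells, the secretory cells of the airway, at 122 ± 21.7 (SD, n = 2 for each). Slc16a3 (ENSMUSG00000025161) was highest in a class that carried markers of non-classical monocytes and neutrophils, at 630 ± 68.6, then in ciliated-like airway cells at 413 ± 26.9 and alveolar macrophage-like cells at 177 ± 11.9 (SD, n = 2 for each). The highest class was a single cluster with non-classical monocyte as its best type. Another cluster, of 1731 and 5988 cells, had neutrophil as its best type and was left out of the classes, so its Slc16a3 level is not given here. AT2-like cells held 2.98 ± 1.74 CPM of Slc16a3 (SD, n = 2), the lowest mean of the 22 classes.

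Against the mean of log levels over the other classes, Slc16a1 was higher in mesothelial-like cells by 5.71 ± 0.124 on the log2 scale (SE; adjusted p = 1.22e-29), in AT2-like cells by 2.75 ± 0.140 (adjusted p = 1.77e-18), in club-like cells by 1.43 ± 0.188 (adjusted p = 3.73e-08) and in T cell-like cells by 1.42 ± 0.201 (adjusted p = 1.56e-07), by edgeR's quasi-likelihood test. In arithmetic means of CPM after TMM scaling, club-like and T cell-like cells, at 115 and 114, lay below the other classes, at 141 each with mesothelial-like cells included. Slc16a1 was lower in all 5 endothelial classes, by log2 values from -1.01 in venous-like to -2.06 in general capillary-like cells. It was also lower in monocyte and neutrophil-like, AT1-like and pericyte-like cells, at -1.33, -0.94 and -0.66 (edgeR, adjusted p = 0.00719, 0.000316 and 0.0188). In alveolar macrophage-like cells Slc16a1 was higher by 0.63 (edgeR, adjusted p = 0.00699). Slc16a3 was higher in the monocyte and neutrophil-like class by 4.64 ± 0.142 (edgeR, adjusted p = 4.72e-25), in ciliated-like cells by 3.95 ± 0.125, in alveolar macrophage-like cells by 3.12 ± 0.134, in club-like cells by 2.29 ± 0.154 and in dendritic-like cells by 1.56 ± 0.182. It was lower in AT2-like cells by a log2 value of -3.22 ± 0.282 (edgeR, adjusted p = 3.66e-12), which rested on 4 and 15 counts and was -3.00 and -2.57 in the single sections, in alveolar fibroblast-like cells by -2.20 ± 0.299 and in AT1-like cells by -2.11 ± 0.242. In club-like cells without any transcript of 6 ciliated markers, Slc16a3 stood at 64.7% and 48.3% of the level of all club-like cells in the 2 sections. The rise in club-like cells thus cannot be told apart from transcripts of ciliated cells.

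**Figure D2:**
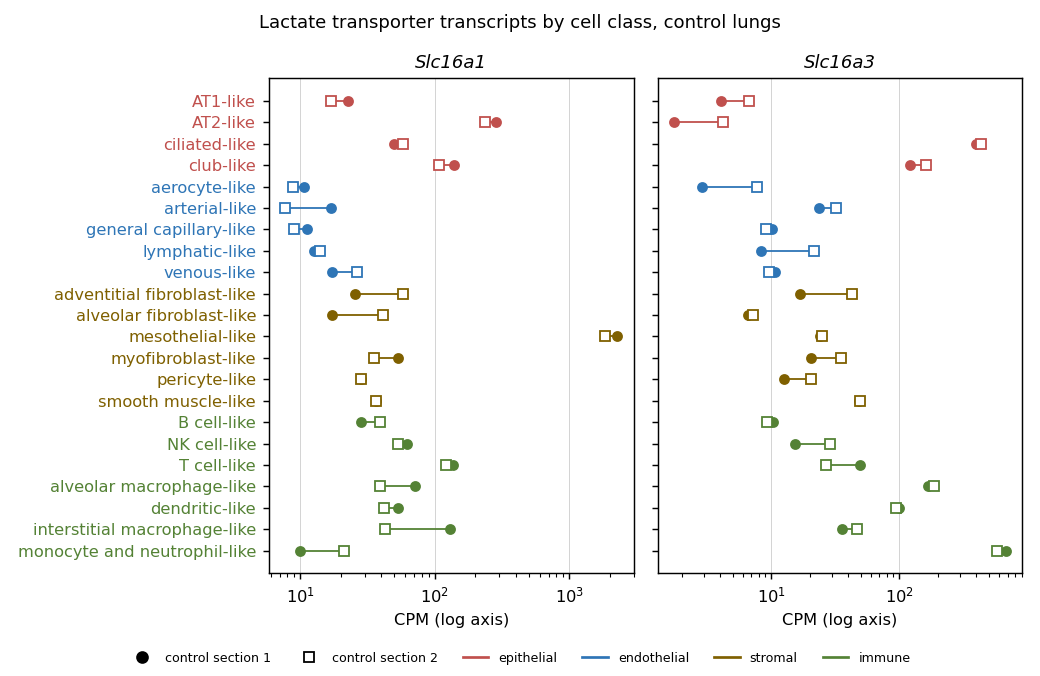
CPM (x axis, log scale) of Slc16a1 and Slc16a3 in each of 22 cell classes (y axis, coloured by compartment) of the control lungs. Filled circles are control section 1, open squares control section 2, and a line joins the sections; Slc16a1 peaks in mesothelial-like cells at a mean of 2048, and Slc16a3 in monocyte and neutrophil-like cells at a mean of 630.

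The subunits of lactate dehydrogenase, which converts pyruvate and lactate into each other, were also unevenly spread. Ldhb (ENSMUSG00000030246) reached 10197 ± 901 CPM in club-like cells and 5801 ± 38.2 in ciliated-like cells, against 35.3 ± 1.28 in alveolar macrophage-like cells (SD, n = 2 for each). Ldha (ENSMUSG00000063229) varied less, from 1638 ± 57.6 in club-like cells and 1297 ± 23.5 in alveolar macrophage-like cells to 277 ± 66.0 in pericyte-like cells (SD, n = 2 for each). After TMM scaling, on which the tests rest, alveolar macrophage-like cells were highest in Ldha, at 1687 CPM against 1543 in club-like cells. By edgeR, Ldhb was higher in club-like cells by 5.34 ± 0.0746 on the log2 scale (adjusted p = 2.89e-35) and lower in alveolar macrophage-like cells by -2.75 ± 0.184 (adjusted p = 3.42e-15), where Ldha was higher by 1.69 ± 0.0987 (adjusted p = 7.93e-17). Over the 4 genes and 22 classes, 24 differences were higher, 41 were lower and the rest were not called. Of those called higher, 7 lay below the other classes in arithmetic means of CPM, among them Ldhb in AT1-like, smooth muscle-like and mesothelial-like cells. Slc16a7, Bsg and Emb are not on the panel.

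**Figure D3:**
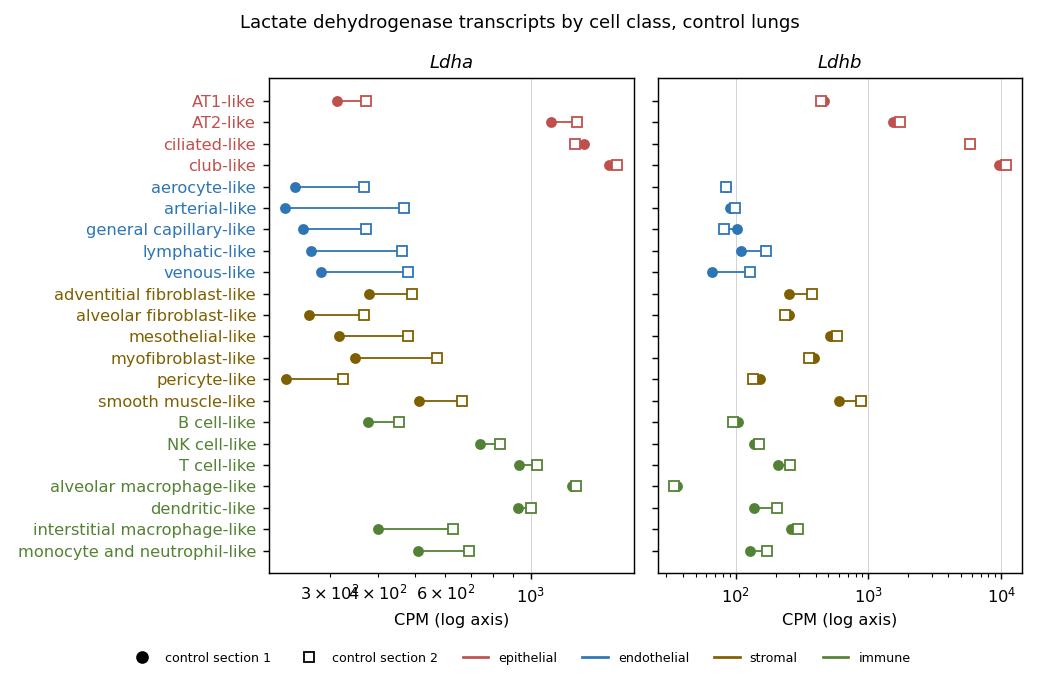
CPM (x axis, log scale) of Ldha and Ldhb in each of 22 cell classes (y axis, coloured by compartment) of the control lungs. Filled circles are control section 1, open squares control section 2, and a line joins the sections; Ldhb spans from 35.3 in alveolar macrophage-like to 10197 in club-like cells, and Ldha from 277 to 1638.

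By compartment, 203 genes of the 12 fixed lists were tested, on means of log levels over classes. Of 639 calls over the 4 compartments, 27 went the other way in arithmetic means of CPM, among them the rise of Slc16a1 in epithelial classes, with 117 inside and 145 outside. In the mean over the 4 epithelial classes, most genes of lactate transport, mitochondrial oxidation and fatty acid metabolism were higher, which did not hold in AT1-like cells, and most genes of the matrix and of transforming growth factor beta (TGF-beta) signalling were lower. Ldhb was higher by 3.98 ± 0.0590 on the log2 scale (SE; edgeR, adjusted p = 1.04e-33) and Pcx, which carboxylates pyruvate, by 3.40 ± 0.0680 (adjusted p = 3.82e-30). Ptgs2, an enzyme of prostaglandin synthesis, was higher by 2.49 ± 0.186, Pfkfb2, a regulator of glycolysis, by 2.48 ± 0.0553, Cat, the catalase gene, by 2.35 ± 0.0417 and Gpt2, an alanine aminotransferase, by 2.0 ± 0.103. The largest falls were those of Gpr65, an acid-sensing receptor, at -3.28 ± 0.302, and Mmp3, a matrix protease, at -3.13 ± 0.624. Both were near the floor in epithelium, with means of 1.96 and 4.97 CPM, and single sections gave smaller falls, of -2.19 and -2.67 for Gpr65 and -2.50 and -2.66 for Mmp3. In all, 82 genes were higher, 95 lower and 26 not called. The share of all 3414 tested genes that was called is not given here for any compartment, so counts of listed genes have no baseline.

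Of 9 tested genes of lactate transport and pyruvate use, 7 were higher and 1 lower in epithelial classes, both over all genes and adjusted over the list alone (fry, adjusted p = 2.92e-23). The lower gene was Pdk4, an inhibitor of pyruvate oxidation, at -0.98 ± 0.110, and Slc16a3 was not called at 0.26 ± 0.145 (edgeR, adjusted p = 0.0918). Without the ciliated-like and club-like classes Slc16a3 fell, at -2.48 (edgeR, adjusted p = 1.37e-12), and with cells summed per compartment, or without the jointly named classes, it rose, at 1.17 and 0.63 (edgeR, adjusted p = 1.56e-05 and 0.000222). Among 17 glycolysis genes 9 were higher and 6 lower, and adjusted over the list alone the numbers were the same; Aldoa and Pgk1 were higher by 0.60 and 0.73, and Pfkp was lower at -1.19. All 9 called genes of 12 in mitochondrial oxidation were higher (9 adjusted over the list alone; fry, adjusted p = 3.74e-15). Of 21 genes of fatty acid metabolism 14 were higher and 5 lower, also adjusted over the list alone, led by Fasn, the fatty acid synthase, at 1.61 ± 0.0463, with Acsl4 at 1.52 and Acly at 0.99. Of 20 genes of stress and senescence 12 were higher and 5 lower, also adjusted over the list alone; Sod1 and Sod2, which remove superoxide, were higher by 1.61 and 1.41, and Mdm2 by 0.98. Among 16 genes of enzymes that add or remove acyl groups, lactyl groups included, 8 were higher and 3 lower, also adjusted over the list alone, with Acss2, an acetyl-CoA synthetase, at 1.67, Sirt3 at 1.15, Kat5 at 0.66 and Kat2b at 0.36. The rise of Sirt3 ended without the airway classes (edgeR, adjusted p = 0.815).

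Each epithelial class was also set against the mean of log levels over all other classes. In AT1-like cells 3 genes of fatty acid metabolism were higher and 13 lower, with a median of -0.34, against 15 and 2 in AT2-like, 14 and 6 in club-like and 10 and 6 in ciliated-like cells. Of the lactate transport and pyruvate genes 4 were higher and 5 lower in AT1-like cells, against 7 and 2 in AT2-like, 8 and 1 in club-like and 7 and 0 in ciliated-like cells. For mitochondrial oxidation the numbers were 4 and 4 in AT1-like cells, against 7 and 0, 9 and 0, and 8 and 1. For TGF-beta signalling they were 14 and 13 in AT1-like cells, against 8 and 17, 5 and 23, and 3 and 24 in the same order. These numbers were the same adjusted over the list alone, except 6 in place of 5 higher TGF-beta genes in club-like cells.

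In epithelial classes 25 of 27 matrix genes were lower and 1, P4hb, was higher by 0.71 ± 0.0394 (edgeR, adjusted p = 1.14e-17); the numbers were the same adjusted over the list alone. Fbn1, Col5a1 and Postn were lower at -1.93, -2.27 and -1.84. Of 32 genes of TGF-beta signalling 23 were lower and 7 higher, also adjusted over the list alone, among them Tgfb1 at -2.90, the receptor genes Acvrl1 and Eng at -2.89 and -2.69, and Ltbp1 at -1.91. Of 20 inflammatory mediators 14 were lower and 3 higher, also adjusted over the list alone; Tnfrsf1b, Tnfrsf1a, Csf1 and Vcam1 were lower at -2.13, -1.26, -2.54 and -2.55. Among 14 hypoxia response genes 5 were higher and 7 lower, also adjusted over the list alone; Bnip3, Egln2 and Vegfa were higher by 1.16, 0.58 and 0.61 and Epas1 lower at -0.53, a fall that ended without the airway classes (edgeR, adjusted p = 0.170). Of 8 genes of acid and base sensing 3 were higher and 5 lower, also adjusted over the list alone, with Slc9a3r1 at 1.42, the proton pump subunits Atp6v1a and Atp6v0a1 at 0.96 and 0.95, and Slc4a7 at -1.15. For hypoxia response and for acid and base sensing the medians were -0.18 and -0.67 and the means -0.21 and -0.51, while fry gave a rise (adjusted p = 0.000249 and 4.41e-06).

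In the mean over the 5 endothelial classes, 16 of 32 genes of TGF-beta and bone morphogenetic protein (BMP) signalling were higher and 8 lower, and all 9 tested genes of lactate transport and pyruvate use were lower. The sodium-coupled lactate transporter gene Slc5a12 went the other way in mean CPM, at 86.9 in endothelial classes against at most 16.4 in the other compartments. Aerocyte-like cells had its highest level and can carry this mean. Levels of Slc5a12 in the other endothelial classes are not given here, so a rise across endothelium is not shown. Slc5a12 had no count in 1 class and was therefore not tested, by a rule chosen after results had been seen. Eng and Acvrl1, co-receptor and receptor of this pathway in blood vessels, were higher by 2.70 ± 0.0434 and 2.66 ± 0.0424 on the log2 scale (SE; edgeR, adjusted p = 1.43e-32 and 1.39e-32). Smad6 and Id1, targets of BMP signalling, were higher by 2.31 ± 0.0614 and 2.21 ± 0.0764. Acacb, an acetyl-CoA carboxylase, and Gpr4, a proton-sensing receptor, were higher by 2.04 ± 0.0998 and 1.89 ± 0.120. The cytokine gene Il18 and Slc16a1 had the largest falls, at -2.39 ± 0.170 and -2.19 ± 0.166 (edgeR, adjusted p = 2.28e-14 and 1.25e-13). In all, 52 genes were higher, 92 lower and 59 not called.

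The counts of TGF-beta signalling genes in endothelial classes were also 16 and 8 adjusted over the list alone (fry, adjusted p = 9.87e-18). Against all other classes, the 2 most frequent endothelial classes had more of these genes lower than higher: 12 were higher and 14 lower in general capillary-like cells (median -0.16), and 11 and 16 in aerocyte-like cells (median -0.31). In arterial-like cells 16 were higher and 8 lower, in venous-like cells 18 and 4, and in lymphatic-like cells 12 and 6. Adjusted over the list alone these numbers changed by 1 at most. All 9 tested lactate transport and pyruvate genes were lower, also adjusted over the list alone (fry, adjusted p = 1.57e-16), with Ldhb at -1.80, Slc16a3 at -1.52, Pcx at -1.40, Ldha at -0.81 and Mpc1, a subunit of the mitochondrial pyruvate carrier, at -0.66. Of 17 glycolysis genes 13 were lower and 1 higher, and of 12 genes of mitochondrial oxidation 10 were lower and 0 higher, both also adjusted over the list alone; Idh1, Idh2, Ogdh and Ppargc1b were lower at -0.81, -0.48, -0.34 and -1.43. Of 21 genes of fatty acid metabolism 6 were higher and 12 lower, of 27 matrix genes 6 and 11, of 20 stress genes 3 and 9, of 7 amino acid synthesis genes 1 and 4, and of 8 acid and base sensing genes 2 and 3, with equal numbers adjusted over the list alone. Among matrix genes, lymphatic-like cells had 18 higher and 0 lower against all other classes (19 and 1 adjusted over the list alone), and general capillary-like cells 1 and 22 (1 and 23). Transcripts of neighbouring cells were not tested as a source of the matrix genes in lymphatic-like cells. Median, mean and fry differed in sign for hypoxia response, with 4 genes higher and 4 lower (-0.033, 0.11, up, adjusted p = 1.1e-07), and for inflammatory mediators, with 9 higher and 7 lower (0.21, -0.11, up, adjusted p = 4.1e-09), both also adjusted over the list alone. They also did for the acylation enzymes, with 4 higher and 2 lower, or 3 and 2 adjusted over the list alone (0.045, -0.039, up, adjusted p = 0.984).

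In the stromal classes, matrix genes stood out. Mmp3 was higher by 3.45 ± 0.220 on the log2 scale (SE; edgeR, adjusted p = 1.29e-15), and the collagen genes Col1a2, Col1a1, Col5a1 and Col6a2 by 3.14 ± 0.0764, 3.07 ± 0.0876, 3.06 ± 0.0757 and 2.82 ± 0.0550. Fbln1, which encodes a fibre-associated glycoprotein, was higher by 2.83 ± 0.0850. The largest falls were those of Aldoc, a glycolytic aldolase, at -1.91 ± 0.283, and Cd36, a fatty acid transporter, at -1.56 ± 0.0671. The fall of Aldoc was -0.78 in section 1 alone, less than that of Cd36 at -1.67, and -1.96 in section 2. In all, 80 genes were higher, 81 lower and 42 not called.

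Of 27 matrix genes 25 were higher and 1 lower in stromal classes, also adjusted over the list alone (fry, adjusted p = 1.58e-19), and of 32 TGF-beta signalling genes 20 were higher and 6 lower, also adjusted over the list alone (fry, adjusted p = 5.18e-16). Against all other classes, pericyte-like cells had 12 matrix genes higher and 8 lower, also adjusted over the list alone, with a median of -0.019. Slc16a1 was higher by 0.94 ± 0.140 (edgeR, adjusted p = 4.10e-07), but without the mesothelial-like class it stood at -0.011 (edgeR, adjusted p = 0.966). Ldhb was higher by 0.36 ± 0.0682 in the mean of log levels with each class weighted equally (edgeR, adjusted p = 2.54e-05) and stood at -0.11 with cells summed per compartment (edgeR, adjusted p = 0.313), and its arithmetic mean over stromal classes was lower, at 381 CPM against 1190.0. Slc16a3 was lower at -0.53 ± 0.142 and Ldha at -0.71 ± 0.0630. The fall of Slc16a3 ended without the airway classes or the jointly named classes (edgeR, adjusted p = 0.491 and 0.432). Over 9 genes of lactate transport and pyruvate use 3 were higher and 5 lower, or 6 lower adjusted over the list alone, with a median of -0.19, a mean of 0.032 and a downward direction by fry that did not pass (adjusted p = 0.0607). Of 17 glycolysis genes 2 were higher and 10 lower, of 12 genes of mitochondrial oxidation 1 and 9, of 21 genes of fatty acid metabolism 5 and 13, of 8 acid and base sensing genes 1 and 5, of 16 acylation enzymes 1 and 6, of 7 amino acid synthesis genes 1 and 4, and of 20 inflammatory mediators 9 and 7, with equal numbers adjusted over the list alone. Against all other classes, smooth muscle-like and mesothelial-like cells had more glycolysis genes higher than lower, at 7 and 2 and at 5 and 2, also adjusted over the list alone. Single stromal classes may also differ from the mean on mitochondrial oxidation and fatty acid metabolism, for which their numbers are not given here. The hypoxia response genes, with 5 higher and 6 lower also adjusted over the list alone (median -0.027, mean 0.29, fry up, adjusted p = 0.667), differed in sign. So did the stress genes, with 7 higher and 9 lower, or 7 and 10 adjusted over the list alone (median -0.10, mean 0.015, fry down, adjusted p = 0.00133).

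In the mean over the 7 immune classes, more glycolysis genes were higher than lower and most matrix genes were lower, and single classes went the other way on both lists. Gpr65, the acid-sensing receptor with the largest fall in epithelium, was higher by 4.14 ± 0.152 on the log2 scale (SE; edgeR, adjusted p = 2.72e-22). The chemokine gene Ccl3 was higher by 3.70 ± 0.266 (2.89 and 3.16 in the single sections), the inflammasome gene Nlrp3 by 3.18 ± 0.645 and the tumour necrosis factor receptor gene Tnfrsf1b by 2.77 ± 0.0614. The protease genes Mmp9 and Mmp12 were higher by 2.60 ± 0.383 and 2.42 ± 0.239. Ccn2, a matricellular target of TGF-beta, and Ptgs2 had the largest falls, at -2.03 ± 0.115 and -2.03 ± 0.254. In all, 61 genes were higher, 96 lower and 46 not called.

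Of 17 glycolysis genes 10 were higher and 2 lower in immune classes, also adjusted over the list alone (fry, adjusted p = 5.17e-14), and 7 of 12 genes of mitochondrial oxidation were higher and 2 lower, also adjusted over the list alone (fry, adjusted p = 0.0122). Such counts rest on the mean over the immune classes, which 1 class can carry. Numbers for single immune classes follow for glycolysis, matrix and TGF-beta genes, and not for mitochondrial oxidation or stress genes. Of 7 genes of amino acid synthesis 4 were higher and 2 lower, also adjusted over the list alone; Glud1, Psat1 and Got2 were higher by 0.58, 0.99 and 0.24 and Prodh, which breaks down proline, lower at -1.08. Of 27 matrix genes 21 were lower and 3 higher, and of 32 TGF-beta genes 24 were lower and 4 higher, both also adjusted over the list alone. Against all other classes, matrix genes rose in 2 of the immune classes: 22 were higher and 1 lower in interstitial macrophage-like cells (median 1.19), and 18 and 2 in dendritic-like cells (median 0.82). Whether transcripts of neighbouring cells contributed to these matrix counts was not tested. Glycolysis genes were more often lower than higher in B cell-like cells, with 2 higher and 8 lower, and in interstitial macrophage-like cells, with 2 and 5, against 11 and 3 in alveolar macrophage-like cells. These numbers were the same adjusted over the list alone. In interstitial macrophage-like cells 11 TGF-beta genes were higher and 10 lower (12 and 10 adjusted over the list alone). In the mean over immune classes, Slc16a3 was higher by 1.53 ± 0.155 (edgeR, adjusted p = 1.07e-10) and Ldha by 0.55 ± 0.0566, and Ldhb was lower at -1.60 ± 0.0737. By class, Ldha was higher in alveolar macrophage-like, T cell-like, dendritic-like and NK cell-like cells and lower in B cell-like cells, at -0.50 ± 0.129. Slc16a3 was higher in monocyte and neutrophil-like, alveolar macrophage-like and dendritic-like cells. It was not called in interstitial macrophage-like cells and stood at 9.85 CPM in B cell-like cells, the most frequent immune class. Slc16a1 was not called at 0.21 ± 0.141 (edgeR, adjusted p = 0.172) with equal weight per class, and was lower at -0.32 with cells summed per compartment (edgeR, adjusted p = 0.0209). It was higher by 0.60, 0.35 and 0.57 without the mesothelial-like class, the airway classes or the jointly named classes (edgeR, adjusted p = 0.000730, 0.0367 and 0.00132). By class, Slc16a1 was higher in T cell-like and alveolar macrophage-like cells and lower in monocyte and neutrophil-like cells. Of 14 hypoxia response genes 4 were higher and 7 lower, of 16 acylation enzymes 3 and 7, and of 20 stress genes 5 and 11, all also adjusted over the list alone, and of 8 acid and base sensing genes 3 and 2, or 3 and 1 adjusted over the list alone. Median, mean and fry differed in sign for lactate transport and pyruvate use, with 3 genes higher and 3 lower (0.034, -0.056, down, adjusted p = 0.000555), and for inflammatory mediators, with 8 higher and 9 lower (-0.054, 0.53, up, adjusted p = 8.62e-06), both also adjusted over the list alone. They also did for fatty acid metabolism, with 7 higher and 6 lower, or 7 and 5 adjusted over the list alone (-0.010, 0.023, up, adjusted p = 0.345).

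**Figure D4:**
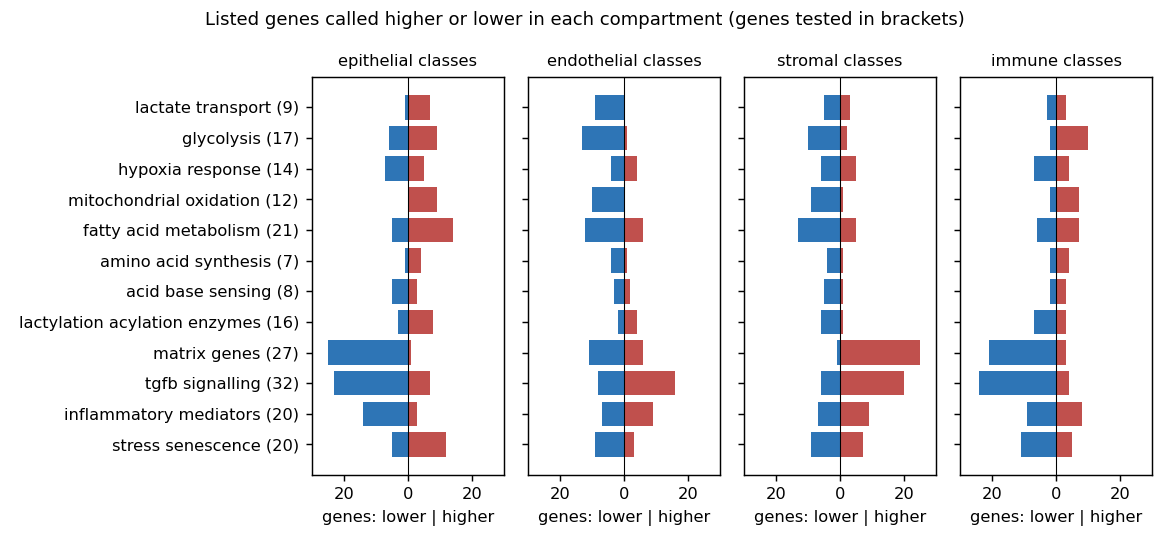
Number of listed genes called higher (right, red) or lower (left, blue) in the classes of each compartment than in the others (x axis, number of genes) for the 12 gene lists (y axis, genes tested in brackets), control lungs. Of 27 matrix genes 25 were lower in epithelial and 25 higher in stromal classes, and all 9 tested genes of lactate transport and pyruvate use were lower in endothelial classes.

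All 22 classes came from the same 2 sections, and the 21 residual degrees of freedom of the edgeR tests describe how these sections differed over the classes, not the spread over animals. A median of 11.4 prior degrees of freedom, shared over genes, came on top. Classes were fixed terms, so the p-value of a compartment leaves out how far its own classes differ. Counts of a class can also hold transcripts of neighbouring cells, since each transcript was assigned by segmentation.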

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

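The test of decoding errors below was chosen after the counts by class had been seen, and the test against more abundant genes before its result was seen. Of the features that are not genes and that no comparison used, 4 had counts over 10 times those of the highest negative control probe in both control sections. That probe had 12 counts in control section 1 and 20 in control section 2. DeprecatedCodeword_16059 had 2399 and 5268 counts, DeprecatedCodeword_0321 had 970 and 3779, DeprecatedCodeword_15560 had 613 and 1505, and UnassignedCodeword_4820 had 250 and 374. In all, 30 such features lay above the highest negative control probe in both sections.

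Of the 3 with a count in every class of both sections, DeprecatedCodeword_0321 differed most between classes. It was highest in interstitial macrophage-like cells, at 560 ± 177 CPM, and adventitial fibroblast-like cells, at 458 ± 97.9, against 20.6 ± 1.82 in aerocyte-like cells (SD, n = 2 for each). The highest class stood 56.6 times above the lowest in section 1, where the lowest class had 1 count, and 31.3 times in section 2. Errors spread at random over all transcripts would leave classes alike, so random errors may be set aside as the whole cause. For DeprecatedCodeword_16059 these ratios were 1.77 and 1.88. That even spread does not mark its counts as random errors, since unassigned codewords had means of only 0.395 and 0.840 counts in the sections. Misreading of a single panel gene at least 10 times as abundant is also argued against. Among such genes, Col1a2 followed the codeword best over the 44 libraries, with r = 0.781 across classes that are not independent replicates. Between the 2 sections the codeword itself had r = 0.945 over the 22 classes. Less abundant genes were outside this test, among them C4b at r = 0.820, and joint misreading of several genes was not tested. Igf1, of similar abundance, had r = 0.924, so a probe that shares targets or expression with it stays open and untested, and no biological explanation was tested.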

How the results depend on the processing

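Leaving out the mesothelial-like class, the airway classes or the jointly named classes, both other rules for genes with a class at 0, and the addition of left-out clusters to compartments were tests chosen after results had been seen. Counts of called genes per compartment, and those summed over classes for all listed genes and for the 4 lactate genes, moved by at most 1.5 times under the alternatives run for them. Cells summed and classes left out were run for compartments only. Of the 639 compartment calls, 622 were shared with RLE factors, 601 with library totals alone, 620 with DESeq2, 616 at a posterior of at least 0.99, 596 without the section term, 542 with cells summed per compartment and 564 without the airway classes.

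With library totals alone, uncalled values changed sign: Slc16a1 in dendritic-like cells to 0.066, and Slc16a3 in arterial-like cells to -0.048 and in myofibroblast-like cells to 0.036. With cells summed per compartment, Ldhb in stromal classes went to -0.11 and Slc16a1 in immune classes to -0.32. Without the airway classes, Slc16a3, Epas1 and Sirt3 in epithelial classes went to -2.48, 0.16 and -0.030, and without the mesothelial-like class Slc16a1 in stromal classes went to -0.011; here the class left out carried the value. For the other changes the cause was not tested. Of 2494 values of single genes under the alternatives, a further 15 lost their call and 10 gained one without a change of sign. With a section left out, which gives a value with no test, 37 and 45 of 178 values lay further than the SD of both sections from the fitted value. None of the called ones changed sign. These values are contrasts of log CPM with a prior count of 2, which draws sparse genes towards 0, and the fitted value is another estimate. A single section always lies within the SD from the mean of both. The numbers 37 and 45 thus need a gap between the estimates and do not measure dependence on a section.

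At 40 transcripts per cell the epithelial share was 16.2%. At a posterior of at least 0.99 it was 20.4%, the stromal share 14.1%, the immune share 18.5%, the endothelial share 18.1%, general capillary-like cells 7.02% and the share outside named classes 28.9%; cells assigned with less certainty leave the total there. With the clusters under 0.7 of the best marker score added to compartments, the epithelial share was 30.4%, the endothelial 26.8%, the stromal 22.2%, the immune 20.2% and the share outside 0.362%, since more cells are then counted. Leaving out the sections of 1 number, a value with no test, gave differences in cells from 32807 to 162083 for bleomycin against control, from -101376 to -28296 for AZD3965 and from -136053 to -35937 for VB124 against bleomycin. The numbers of sections share only a number: the first section deviated by -34538 cells in controls and by 30100 in the bleomycin group. With the replicate number as a block, the 4-group exact permutation p was 0.0833, against 0.210 on log2 numbers, and each pairwise p was 0.5. Depth in section 1, with a median of 141 transcripts per cell, limits genes near the negative probes.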

Other observations

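The genes in the next paragraphs were chosen after their values were seen, as were both explanations given for the cell numbers, which were not tested. The bounds for the tests of neighbouring transcripts were set before those results were seen. For some of the 23 listed genes without a test, the class with the highest mean level is given. Slc5a12, a sodium-coupled lactate transporter, stood at 308 ± 72.5 CPM in aerocyte-like capillary cells (SD, n = 2). Ppargc1a, a regulator of mitochondrial genes, stood at 191 ± 36.9 in ciliated-like cells (SD, n = 2). Shmt1, an enzyme of one-carbon metabolism, reached 259 ± 61.1 in club-like cells, Csf2, a growth factor for alveolar macrophages, 110 ± 57.8 in AT2-like cells, and the proteoglycan gene Vcan 475 ± 92.2 in adventitial fibroblast-like cells (SD, n = 2 for each). The chemokine gene Ccl8 was at 479 CPM in section 1 and 1753 in section 2 in interstitial macrophage-like cells.

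Alveolar macrophage-like cells had 96 listed genes higher and 81 lower, out of 203, than the mean of log levels over the other classes. The cytokine genes Il1rn and Il18 were higher by 7.31 ± 0.144 and 6.97 ± 0.0864 on the log2 scale (SE; edgeR, adjusted p = 1.72e-30 and 7.84e-36). Of 21 genes of fatty acid metabolism 14 were higher and 4 lower, also adjusted over the list alone, among them Pparg at 5.70 ± 0.158, Lpl at 5.07 ± 0.137 and Plin2, a coat protein of lipid droplets, at 4.68 ± 0.0714. In club-like cells, Pcx was higher by 4.61 ± 0.0876 and Acss2, which makes acetyl-CoA from acetate, by 3.69 ± 0.112 (edgeR, adjusted p = 1.71e-30 and 1.37e-24).

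Transcripts of a stronger neighbour could account for lactate genes in some classes, and each class was therefore measured again in cells without any transcript of the neighbour's markers. Slc16a1 in T cell-like cells kept 98.5% of its level or more in both sections without AT2 markers, Ldhb in AT1-like cells 94.4% without AT2 markers, and Slc16a3 in dendritic-like cells 98.9% without alveolar macrophage markers, which argues against these neighbours as the main source. Slc16a3 in club-like cells kept 64.7% in section 1 and 48.3% in section 2 without ciliated markers, between the bounds of 25% and 50% in the latter. Ciliated markers in club-like cells stood at 22.3% and 24.7% of their level in ciliated-like cells. The same shares of the ciliated Slc16a3 level would be 87.9 and 107 CPM, against 121 and 162 in all club-like cells. There, ciliated transcripts and expression in the club-like cells cannot be told apart. No biological explanation was tested.

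The number of segmented cells in the bleomycin sections was 1.46 times the mean of the other 6 sections. A larger area of tissue in those sections could account for this, and so could a higher number of cells after injury without an inhibitor. These cannot be told apart, since the area of each section was not used here and the slide is unknown.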
